A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

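Per the series title, the single-stranded DNA binding protein RPA was measured by chromatin immunoprecipitation on microarrays in fission yeast (Schizosaccharomyces pombe). The labels name the channels IP and input, but give the molecule as total RNA and describe an RNA extraction. The arrays were read as immunoprecipitated and input DNA, an assumption on which the meaning of every value rests. Per the series title, the precipitated subunit was Ssb1, the large subunit of RPA. Per the labels, 3 arrays came from a cdc25-22 strain and 3 from a cdc25-22 rad3∆ strain; the first group carries the name WT in the labels and is called WT here, although it is a cdc25-22 mutant. The label of the input channel of rad3∆ replicate 3 gives the allele as cdc25-23, and that array was kept with the other rad3∆ arrays. Per the labels' protocols, cells grew at 25 °C, were held for 4 h at 36.5 °C, were shifted back to 25 °C for release and were treated with 6 mM HU (hydroxyurea). All titles also carry the number 60, whose unit the labels do not state. The labels do not say whether the 3 replicates of a strain are separate cultures. The p-values of tests between arrays therefore measure the spread between these arrays and no more. The set test camera compares windows or genes with others, and Fisher's exact test counts regions. Their p-values are not a measure of agreement between arrays.

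Each array compared the immunoprecipitated DNA (IP) with its own input DNA in 2 colours. Per the labels, the IP carried the 555 dye and the input the 647 dye in replicates 1 and 2 of both strains, and the IP carried Cy5 and the input Cy3 in replicate 3. The IP was thus in the green channel on 2 arrays and in the red channel on 1 array of each strain, and the dye chemistry changed together with the orientation.

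The authors deposited an Agilent Feature Extraction output for each array. Per the file headers, the processed signals are intensity values that the software had background-subtracted, spatially detrended and dye-normalized with a linear factor under protocol CGH_107_Sep09. Values had not been scaled between arrays. The deposited log10 ratio column is red over green processed signal; checked on each array, at least 99.7% of probes matched that ratio within 0.01 log2 units. The software version was 10.7.1.1 in the headers of both replicate 1 arrays and 10.7.3.1 in the other headers and in the submitters' processing notes. Same-numbered arrays of the 2 strains lay on the same slide, per the file headers. Of the columns read, 0 were left unused.

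Probe positions are those of the array design, which the file headers place on an NCBI build of Schizosaccharomyces pombe labelled Feb2002. The design holds 42707 probes of 45 to 60 bases, of which 42641 are nuclear, with a median spacing of 265 bp. Since the files hold no probe sequences, the positions were compared with the ASM294v3 reference through the base composition around each probe in segments of 100 kb. Of 126 segments, 107 matched without an offset. The other 19 were all on chromosome I from 3700001 onward, where the clear offsets were 6145 to 6153 bp. No gene names were used there, and reference sequence only, read at these offsets, in a search for second copies near the right end. Genes, A+T-rich islands and other annotated features therefore cover 36405 probes (85.4%). Coordinates are array positions, counted from 1.

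From the processed signals, log2(IP/input) was computed per probe, and each array was centred on its median nuclear probe. A value of 0 is thus the array median and not absence of RPA. The 211 nuclear probes with an outlier flag in any array were left out, which left 42430. Probes were averaged in 1 kb windows with at least 2 probes, which gave 12039 windows with a median of 4 probes. The same averages were taken over annotated genes (8196 genes with at least 2 probes, of which 4144 code for proteins).

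All 6 arrays entered each limma fit, with a mean per strain and a term for dye orientation, and tests were two-sided with Benjamini-Hochberg adjustment. The fits had 3 residual degrees of freedom and, for windows, 8.22 prior degrees of freedom for the ratio and 3.09 for the input. A window or gene was called enriched at an adjusted p under 0.05 with a fitted log2 value of at least 0.5 (1.41-fold), and depleted at or below -0.5. Fitted values weigh both dye orientations equally and so differ slightly from plain means over arrays. Strain differences are rad3∆ minus WT and were called at an adjusted p under 0.05. Regions were runs of at least 2 enriched windows, joined over at most 1 window. Shared regions were called in the same way on the mean of the strains, blind to their difference. For single values per array, exact permutation tests were used, whose smallest two-sided p for 3 arrays against 3 is 0.10. All of these tests shuffle the 6 arrays freely and so ignore the pairing by slide described below.

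Gene lists and region classes were tested with camera from limma, with a preset correlation of 0.01. The lists included targets of the MBF transcription complex, histones, stress response, heat shock, glycolysis and translation factors, ribosomal proteins, replication factors, checkpoint, repair and recombination, mitotic forkhead cluster, Tf2 retrotransposons and the wtf spore killer family. No Tf2 element was measured (0 of 13). A further list that was tested, and a gene that the naming rule below would give, are not reported here. The classes were A+T-rich islands, control intergenic sites, tRNA genes, long terminal repeats (LTR), windows within 50 kb of a chromosome end, snRNA and snoRNA genes, and ribosomal protein genes. Right ends were those of the reference sequence on chromosomes II and III and the last probe on chromosome I. Whether DNA missing from the reference lies beyond an end was not examined, so distances from an end are not distances from a telomere. The islands were the 400 most A+T-rich intergenic stretches of 500 bp, at least 2 kb apart, of which 324 lie in the matching part. They stand in for replication origins and were taken from sequence alone. Centromeric repeats were not tested because the annotation marks none. In the strain comparisons the text names the 10 largest rises and the 10 largest falls past the threshold with the same sign on all 3 slides, or the 5 largest each way when none passed. For enrichment it names the 5 regions per strain with the highest window, and for each list up to 3 members with the highest enrichment and up to 4 with the largest strain difference. The deleted gene rad3 is always given. Lists, classes and this rule were fixed before the data were examined. So were the main tests and the alternatives, other than those described as chosen or added after values were seen. Tests of single chromosome arms, of islands against control sites and of islands in called regions were not among those fixed beforehand. Nor were those under other observations, except that of the last hypothesis there.

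The replicate numbers were checked for pairing. Across windows, the deviations of same-numbered arrays from their strain means correlated at 0.34, 0.31 and 0.51, all over 0.1, so the numbers pair the arrays. The pairing coincides with the slide. The fit with replicate number as a block was an alternative fixed beforehand, and its values stand beside the results that it changes.

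Alternatives tried were no dye term, the replicate or slide block, normexp background correction with an offset of 50, loess within arrays, mode centring, scaling to equal spread, probes well above background, no saturated probes, a GC correction, 0.5 and 2 kb windows, thresholds of 0.3 and 1, single probes, the union of the regions, an estimated correlation in camera, other numbers of islands, and leaving out each array. Normexp used the median spot signals, because the files hold no mean signals. Loess has no value for the input, which is a single channel. For arrays, the number of arrays limits the precision.

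The scripts were tested on simulated data with the residual spread of the real windows. The simulated noise was independent between windows and arrays, whereas the deviations of same-numbered real arrays correlate. The rates that follow are thus those of the simulation. For the strain difference over 12039 windows, 1.18% of changes of 0.5 log2 units, 57.2% of changes of 1 and 80.8% of changes of 1.5 were recovered, with 15 false calls among 59195 unchanged windows. Small strain differences at single windows were therefore mostly out of reach of this design. The R package data.table was at version 1.17.8. The other versions were R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, Matplotlib 3.10.9 and BLAST+ 2.17.0.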

Results

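RPA coats single-stranded DNA, which builds up at replication forks that stall when HU (hydroxyurea) starves cells of deoxyribonucleotides. Read as immunoprecipitated DNA over input DNA, the series measured where RPA sat along the genome of fission yeast held in HU, with and without Rad3, the checkpoint kinase of the ATR family. The cdc25-22 allele is temperature-sensitive in the phosphatase that drives entry into mitosis, and the shift to 36.5 °C and back served to synchronise the cells of both strains. Each strain had 3 arrays, so that 3 is the n behind every mean, and the number of arrays limits the precision. The median background-subtracted IP signal was 445, 241 and 788 on WT arrays 1, 2 and 3, and 635, 41.5 and 1145 on rad3∆ arrays 1, 2 and 3. The dim rad3∆ array 2 had 79.6% of its probes well above background in the IP channel, while the highest share was 99.5% on rad3∆ array 1. Values below are log2(IP/input) relative to the array median, given as mean ± SD unless said otherwise.

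The deleted gene was checked first, because it tests the strain labels. The rad3 gene (SPBC216.05) lies on chromosome II from 904184 to 913629, and 24 of its 32 probes, from 904607 to 911114, lost their signal in the rad3∆ arrays. Input signal over this segment of 6.51 kb was -0.30 ± 0.08 log2 units from the array median in WT (SD, n = 3) and -5.67 ± 1.31 in rad3∆ (SD, n = 3; exact permutation p = 0.10, the smallest that 3 arrays against 3 can give). None of the 24 probes stood well above background in the input of any rad3∆ array (0 of 24 in each). With both channels at the floor, the size of the input loss is set by that floor and the ratio there has no meaning as RPA, although it read 1.12 ± 0.50 in rad3∆ (SD, n = 3) and -0.48 ± 0.12 in WT (SD, n = 3). The neighbouring gene swi1, which encodes a fork protection factor, overlaps the lost segment with its annotated transcript, and its ratio is affected in the same way.

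**Figure D1:**
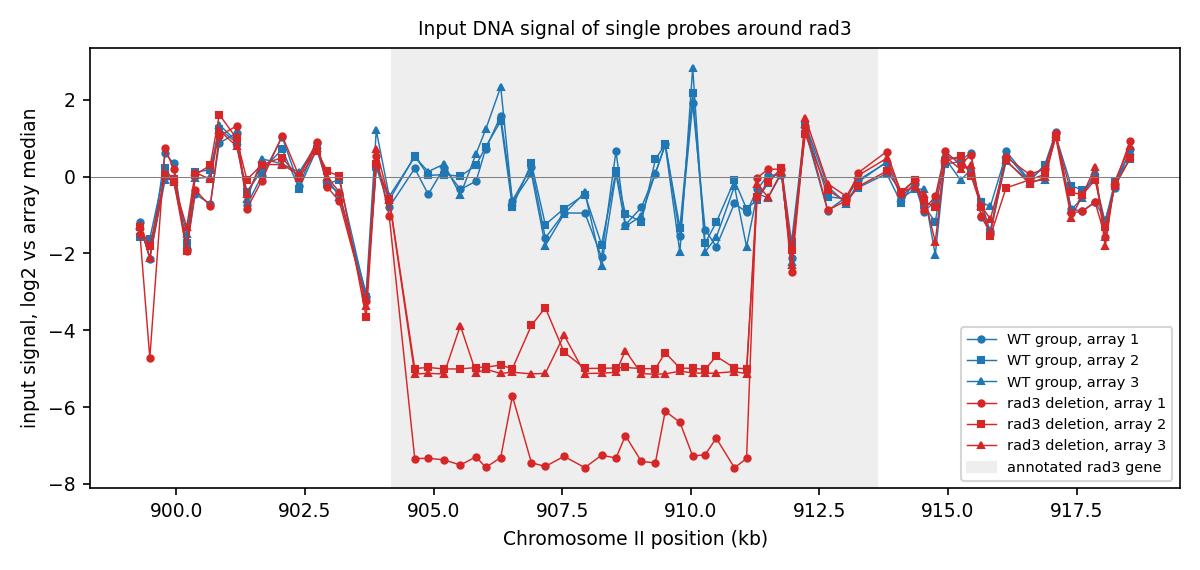
Input DNA signal (log2, relative to the array median) of single probes against position on chromosome II (kb), with 1 line per array, WT in blue, rad3∆ in red and the annotated rad3 gene shaded. Across the segment from 904607 to 911114 the rad3∆ arrays lie at a mean of -5.67 and the WT arrays at -0.30.

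In WT, the RPA regions with the highest windows lay at genes of many kinds. The highest window (1.80 ± 0.12, fitted value ± SE) was in a region of 11 kb on chromosome I from 3442001 to 3453000, over pkl1 (a kinesin), pfd6 (a prefoldin subunit), rpt5 (a proteasome subunit), dpe1, sod22 (a sodium/proton antiporter) and cul4 (a cullin). Next came chromosome II from 1647001 to 1659000 (1.75 ± 0.11), with yox1, a regulator of S-phase transcription, rec6, dpm2, rps402, kgd4 and crr1. The region at cdc3, the profilin gene (chromosome I, 2578001 to 2580000), reached 1.65 ± 0.15. A 20 kb region on chromosome II from 2018001 to 2038000 reached 1.65 ± 0.12 and spanned orc4, which encodes an origin recognition subunit, together with ppk32, ell1, qcr1 and ccc2. The region over tef3, a translation elongation factor gene, and dal51 (chromosome III, 1684001 to 1699000) reached 1.60 ± 0.12. With limma, 2226 of 12039 windows (18.5%) were enriched and 2500 (20.8%) were depleted, and the enriched windows formed 295 regions of 2316 kb in all, with a median length of 6 kb and a longest region of 52 kb. Centring on the mode of each array, which lay 0.0024 to 0.24 log2 units above the median, moved these counts to 1555 enriched and 3224 depleted windows. The number of enriched windows also followed the chosen threshold, with 3478 at a log2 value of 0.3 and 218 at 1.

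In rad3∆, 3 of the 5 regions with the highest windows lay at positions named for WT. The window at cdc3 reached 1.89 ± 0.15 (fitted value ± SE) in a region from 2578001 to 2585000 that also covered tif303, a translation initiation factor gene, and tom6. The region over rpt5 and dpe1 (chromosome I, 3443001 to 3449000) reached 1.76 ± 0.12, and the region with yox1 (chromosome II, 1647001 to 1659000) reached 1.69 ± 0.11. The remaining pair were chromosome II from 2442001 to 2456000 (1.62 ± 0.12), over ucp3, fnx1, glo1, gfa1 and pst1, and a stretch of 70 kb near the right end of chromosome III, from 2359001 to 2429000 (1.62 ± 0.12), with nnk1, ade5, puf6 and dhm1 among its genes. With limma, 2266 windows (18.8%) were enriched and 2562 (21.3%) were depleted, and the enriched windows formed 335 regions of 2323 kb with a median length of 5 kb. The enriched windows and regions include those over the deleted rad3 segment, where the ratio has no meaning as RPA. Mode centring gave 1652 enriched and 3199 depleted windows, and thresholds of 0.3 and 1 gave 3496 and 220 enriched windows. Of the WT regions, 255 (86.4%) overlapped a rad3∆ region, and 1789 windows were enriched in both strains, against 419 if the calls were independent. The mean profiles of the strains correlated at r = 0.91 across windows, which are not independent replicates. Single arrays correlated at 0.74 to 0.88 within a strain and at 0.69 to 0.90 between strains.

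**Figure D2:**
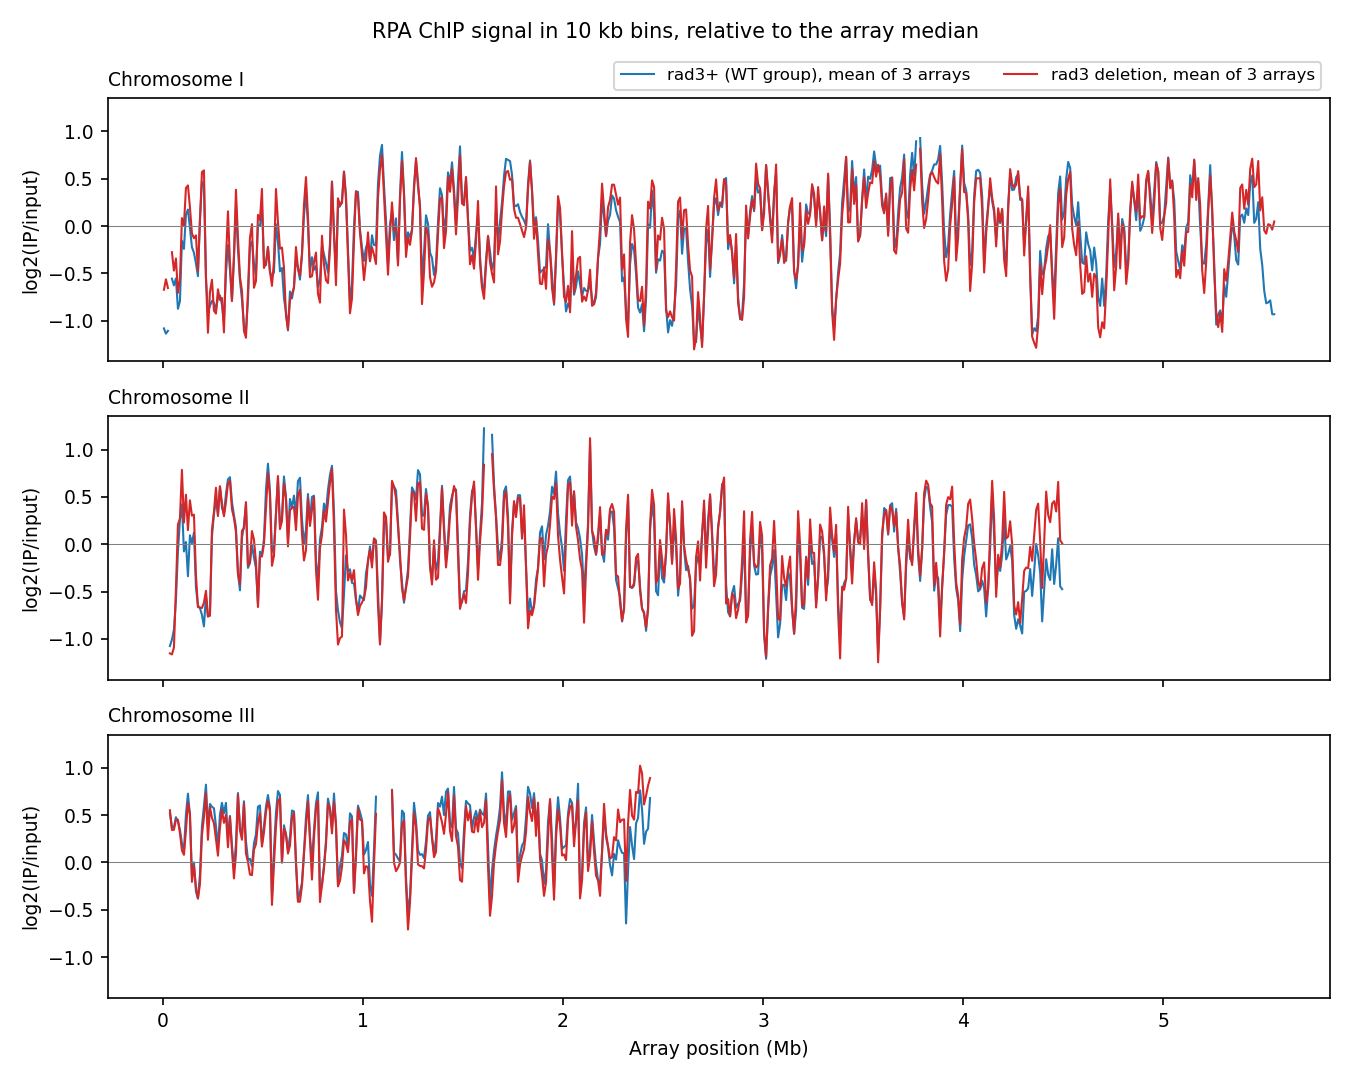
Mean log2(IP/input) of 3 arrays per strain in 10 kb bins against array position (Mb) on chromosomes I, II and III, with WT in blue and rad3∆ in red. The profiles follow each other (r = 0.91 across 1 kb windows), and near several chromosome ends the rad3∆ line lies higher.

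Over gene bodies, camera placed ribosomal protein genes above other genes in both strains (adjusted p = 0.020 in WT and 0.029 in rad3∆), but not with an estimated correlation (0.82 and 0.75). Of 86 measured, 22 were enriched and 4 depleted in WT, and 25 were enriched and 6 depleted in rad3∆; of all 4144 protein-coding genes, 683 were enriched in WT and 670 in rad3∆. The members with the highest enrichment were rps1701 (1.16 ± 0.14 in WT and 0.97 ± 0.12 in rad3∆; SD, n = 3), rpl3802 (1.13 ± 0.42 and 0.97 ± 0.30) and rpl3202 (0.92 ± 0.21 and 0.90 ± 0.16). A GC correction (0.070 and 0.095) or probes well above background alone (0.084 and 0.27) also ended the calls of this list, as did leaving out WT array 1 for WT (0.068) and rad3∆ array 3 for rad3∆ (0.062).

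No other list passed with camera in either strain, with adjusted p of 0.43 or more. Among 5 histone genes, 2 were enriched in WT, hta1 (1.0 ± 0.27; SD, n = 3) and htb1 (0.79 ± 0.10), while in rad3∆ 1 was enriched and 1 was depleted; in WT the list had a median of -0.061 and a mean of 0.21. Of 13 MBF targets, 1 was enriched and 5 were depleted in each strain, and yox1 was high (1.29 ± 0.43 in WT and 0.87 ± 0.08 in rad3∆). Of 22 replication factor genes, 3 were enriched in each strain, among them rfc4 (0.77 ± 0.15 and 0.83 ± 0.31) and mcm3 (0.77 ± 0.26 and 0.66 ± 0.26), and 4 in WT and 3 in rad3∆ were depleted, among them mcm6 (-0.80 ± 0.11 and -1.03 ± 0.41). Of 11 checkpoint genes, 2 were enriched in WT, rad9 (0.76 ± 0.24) and wee1 (0.63 ± 0.18), and 3 in rad3∆, of which 1 was the deleted rad3, and 3 were depleted in each strain. Of 16 repair and recombination genes, 2 were enriched in each strain, rad52 (0.90 ± 0.21 and 0.75 ± 0.17) and fbh1 (0.52 ± 0.18 and 0.47 ± 0.20), and 4 in WT and 3 in rad3∆ were depleted, with nbs1 at -0.99 ± 0.31 and -1.37 ± 0.70. Of 8 genes of glycolysis and translation, 3 were enriched in WT and 2 in rad3∆, led by tpi1 (0.79 ± 0.15 and 0.59 ± 0.41), and 0 were depleted. Of 10 stress genes, 2 were enriched and 3 depleted in WT, and 1 was enriched and 2 were depleted in rad3∆, with atf1 highest (0.61 ± 0.27 and 0.57 ± 0.28). Of 8 heat shock genes, 1 was enriched and 2 were depleted in each strain, and ssa1 read -0.74 ± 0.17 and -0.47 ± 0.35. Of 10 genes of the mitotic forkhead cluster, 1 was enriched in each strain, mid1 (0.50 ± 0.20 and 0.52 ± 0.14), and 2 in WT and 1 in rad3∆ were depleted. Of 10 wtf genes, 5 in WT and 2 in rad3∆ were enriched, with wtf12 highest (0.80 ± 0.27 and 0.60 ± 0.14), and 2 were depleted in each strain. The counts adjusted over the list alone equalled those over all genes in every list. Over all 8196 genes, limma called 1454 enriched and 1726 depleted in WT (976 and 2218 under mode centring), and 1492 and 1678 in rad3∆ (1021 and 2141 under mode centring).

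Classes of sites differed in their mean RPA signal, though no class call held with an estimated correlation. Windows over tRNA genes read 0.55 ± 0.08 in WT and 0.56 ± 0.13 in rad3∆ (SD, n = 3), and 69 and 68 of 117 such windows were enriched. A+T-rich islands, a stand-in for replication origins, read 0.26 ± 0.07 in WT and 0.42 ± 0.14 in rad3∆ (SD, n = 3), whereas control intergenic sites read 0.031 ± 0.0084 and 0.071 ± 0.021. Windows over ribosomal protein genes read 0.19 ± 0.04 and 0.18 ± 0.0014. Windows within 50 kb of a chromosome end read -0.45 ± 0.16 in WT and -0.053 ± 0.049 in rad3∆. In WT the arms of chromosomes I and II were below the array median there. Those of chromosome III were above it, at 0.44 ± 0.09 on the left and 0.29 ± 0.10 on the right. Camera called tRNA genes (adjusted p = 6.4e-11 in WT and 1.2e-11 in rad3∆), islands (1.7e-06 and 1.7e-12) and ribosomal protein genes (0.0018 and 0.0030) as high in both strains, and the ends as low in WT (0.00016) but not in rad3∆ (0.59). With an estimated correlation each call in WT had an adjusted p of 0.33 and each call in rad3∆ of 0.21; neighbouring windows correlated at 0.86 and 0.87. LTR windows (0.28 and 0.083), snRNA and snoRNA genes (0.25 and 0.59) and control sites (0.31 and 0.10) were not called.

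**Figure D3:**
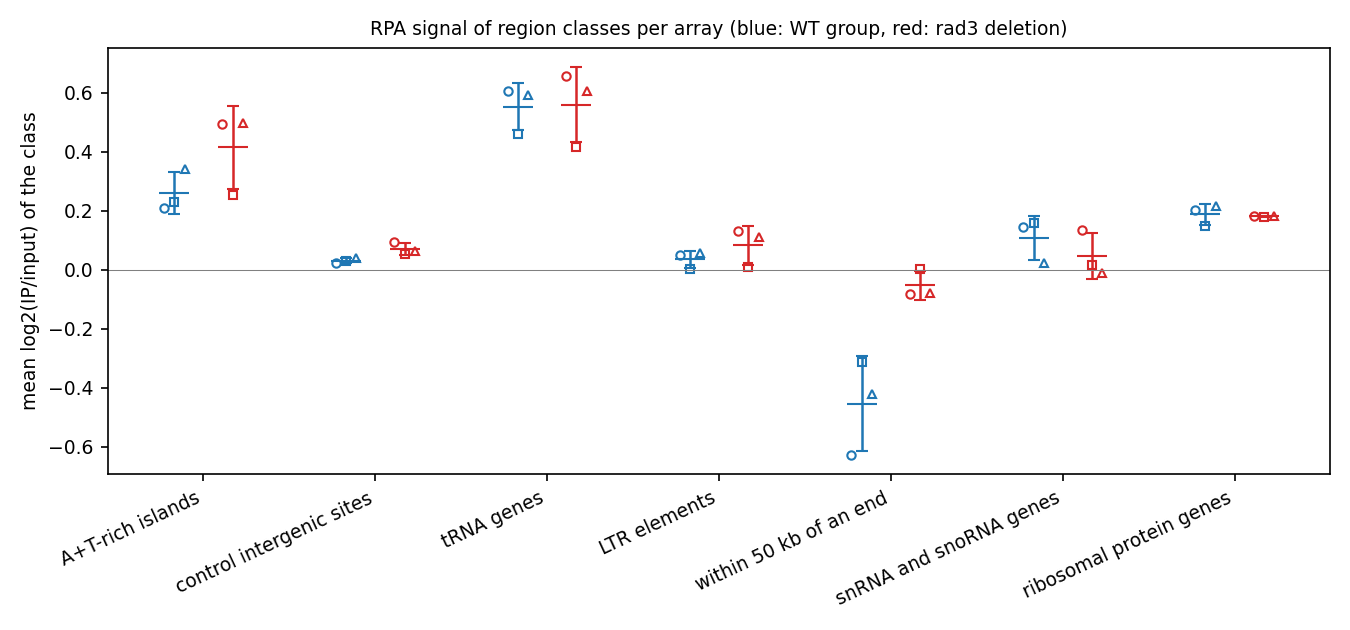
Mean log2(IP/input) of each region class (horizontal axis) per array, with open symbols for the 3 arrays of WT (blue) and rad3∆ (red), horizontal bars for the mean and whiskers for the SD. Windows within 50 kb of an end lie at -0.45 in WT and -0.053 in rad3∆, and A+T-rich islands at 0.26 and 0.42.

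The comparison of the strains asks where RPA depends on rad3. At single windows, 13 of 12039 were higher in rad3∆ and 0 were lower with limma (at an unadjusted p under 0.05, 615 were higher and 361 lower). Of the 13, 4 lay in the deleted rad3 segment and carry no information on RPA. The right end of chromosome I held 6, between 5523001 and 5549000, where RPA rose by 1.03 to 1.15 log2 units. For example, the window from 5541001 to 5542000 read -0.98 ± 0.05 in WT and 0.17 ± 0.10 in rad3∆ (SD, n = 3; limma adjusted p = 0.031). This part of chromosome I has no gene names here, because the array positions do not match the reference. The last 3 lay near the right end of chromosome II: 4453001 to 4455000 covers fub2, which encodes a protein of the PI31 proteasome regulator family (rises of 1.0 ± 0.15 and 1.1 ± 0.16; fitted value ± SE), and 4478001 to 4479000 rose by 0.98 ± 0.15. When windows over the deleted segment were left out, 0 of 12031 passed (608 higher and 361 lower at an unadjusted p under 0.05), with a lowest adjusted p of 0.051. The count of windows higher in rad3∆ was 41 with the replicate block (2 lower), 45 in 2 kb windows (2 lower), 24 with mode centring, 8 with probes well above background, 5 in 0.5 kb windows, 2 with scaled arrays, and 0 with normexp or single probes. It was 5, 0 and 4 without WT arrays 1, 2 and 3, 1, 39 and 4 without rad3∆ arrays 1, 2 and 3, and 241 (48 lower) without both arrays of slide 2. The last of these fits is another model, paired by slide, because dye orientation and slide coincide on the arrays left.

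At shared RPA regions, which were called on the mean of the strains, all calls were rises in rad3∆. A region of this kind need not be enriched in each strain by itself. Over 314 shared regions of 2310 kb, the median per array was 0.63 ± 0.15 in WT and 0.65 ± 0.14 in rad3∆ (SD, n = 3; exact permutation p = 0.80), and the median over regions of the fitted difference, a separate quantity, was -0.010 (medians of -0.0027, 0.064 and -0.056 on slides 1, 2 and 3). RPA rose in rad3∆ at 21 regions and fell at 0 with limma (52 higher and 6 lower at an unadjusted p under 0.05), and each of the 21 was higher on all 3 slides. The largest rise was at epr1, an ER-phagy receptor gene (chromosome I, 2424001 to 2426000), from 0.34 ± 0.02 to 0.94 ± 0.34 (SD, n = 3; limma adjusted p = 0.024). It was followed by rad13, which encodes a nuclease of nucleotide excision repair (chromosome II, 2671001 to 2673000), from 0.21 ± 0.18 to 0.81 ± 0.31, and by the stretch between mug14 and pho841, a phosphate transporter gene (chromosome II, 131001 to 133000), from 0.39 ± 0.16 to 0.97 ± 0.27. The right end of chromosome III (2427001 to 2429000, over SPCC569.05C and SPCC569.04) rose from 0.48 ± 0.19 to 1.04 ± 0.25 (adjusted p = 0.011, limma). Rises of 0.46 to 0.50 were found at cho2, a phospholipid methyltransferase gene (chromosome II, 3945001 to 3947000), alr1 (chromosome III, 2299001 to 2303000), an unannotated stretch of chromosome I (5475001 to 5477000), sod2, the manganese superoxide dismutase gene (chromosome I, 3184001 to 3186000), rbx1, a ubiquitin ligase subunit gene (chromosome I, 1574001 to 1576000), and rrp4 with rsm24 (chromosome I, 562001 to 565000). The other called regions rose by 0.33 to 0.45. In WT the fitted value of the 21 called regions ranged from 0.21 to 0.76, so that some lay under the enrichment threshold of 0.5.

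Regions near the chromosome ends made up much of this set, a comparison chosen after the positions were seen. Of 28 shared regions within 200 kb of an end, 11 rose, against 10 of 286 farther away (Fisher's exact p = 7.2e-08, with regions taken as independent). An A+T-rich island lay in 10 of the 18 called regions with annotation and in 126 of 242 others (Fisher's exact p = 0.81). The count of regions higher in rad3∆ was 54 with the replicate block (8 lower), 35 for the union of the strains' regions, 13 with mode centring (1 lower), 11 with loess or a GC correction, 9 and 5 in 0.5 and 2 kb windows, 7 with probes well above background, 3 with no dye term, and 0 with normexp or a threshold of 1. It was 0 without WT array 1, 2 or 3, 22 without rad3∆ array 1 (2 lower), 56 without rad3∆ array 2 (11 lower), 2 without rad3∆ array 3, and 69 (30 lower) without both arrays of slide 2. Again the fit without slide 2 is paired by slide.

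**Figure D4:**
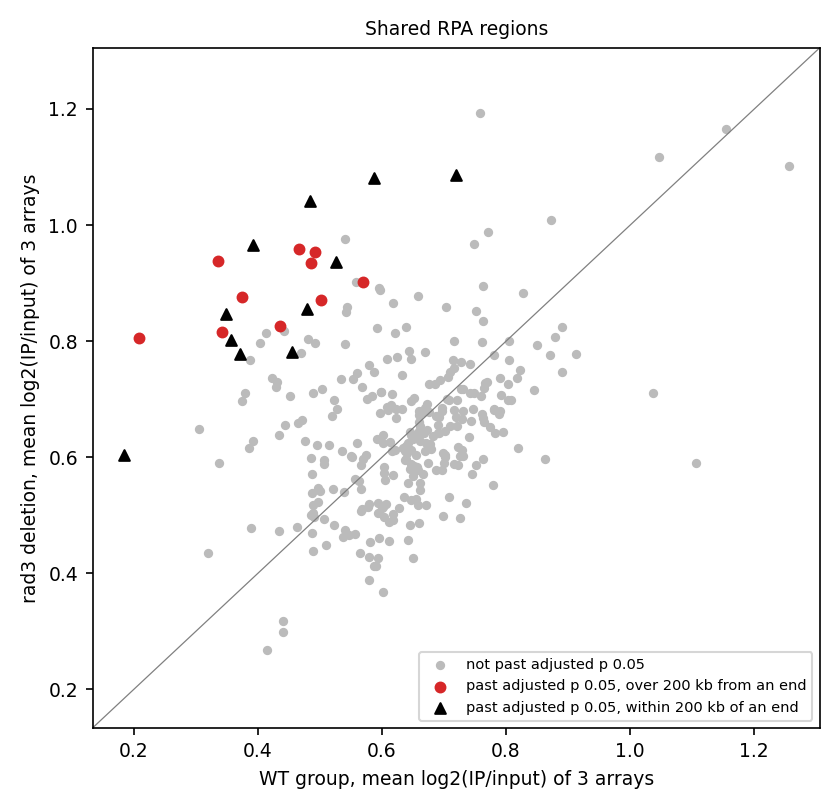
Each point is 1 of 314 shared RPA regions, with the mean log2(IP/input) of 3 arrays in WT on the horizontal axis and in rad3∆ on the vertical axis; the line marks equal values. The 21 regions past an adjusted p of 0.05 all lie above the line, and 11 of them, drawn as triangles, lie within 200 kb of a chromosome end.

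Over gene bodies, 0 of 8196 genes passed for the strain difference with limma (468 higher and 200 lower at an unadjusted p under 0.05), with a lowest adjusted p of 0.096. The largest values that did not pass were positive for rad3 (1.21 ± 0.18, fitted difference ± SE, in deleted DNA), the non-coding RNA genes SPNCRNA.6604 (1.07 ± 0.15), SPNCRNA.1695 (0.99 ± 0.13) and SPNCRNA.5948 (0.97 ± 0.24), and fub2 (1.0 ± 0.12). They were negative for SPNCRNA.2343 (-1.10 ± 0.21), SPNCRNA.5759 (-0.93 ± 0.15), SPNCRNA.3362 (-0.84 ± 0.24), SPNCRNA.5830 (-0.82 ± 0.24) and fex2, a fluoride exporter gene (-0.80 ± 0.14). Among the protein-coding genes alone, fitted as a separate set after the data were seen, fub2 passed (adjusted p = 0.023). Without both arrays of slide 2, in the fit that is then paired by slide, 54 genes were higher and 9 lower.

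No gene list was called for the strain difference with camera. The 5 histone genes had an adjusted p of 0.15 (median -0.27), with htb1 at -0.33 ± 0.14 (fitted difference ± SE) and hta1 at -0.27 ± 0.14. The histones passed with normexp (0.031) and without rad3∆ array 2 (0.045), but with an estimated correlation the adjusted p was 0.63. Stress, heat shock, checkpoint and wtf genes had an adjusted p of 0.37, mitotic forkhead genes, MBF targets, replication factors, repair genes, and glycolysis and translation genes had 0.57, and ribosomal proteins had 0.66. Over all genes, 0 members of any list passed. Adjusted over the list alone, 1 stress gene passed, hsp16 (0.62 ± 0.14; adjusted p = 0.017, limma), a small heat shock protein gene that also passed in the heat shock list (0.014). Among checkpoint genes, rad3 and swi1 passed in the same way (0.0011 and 0.0032), both over deleted DNA; the median of that list was -0.0054 and its mean 0.17. In no other list did a member pass adjusted over the list alone.

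Among region classes, the chromosome ends and the A+T-rich islands were higher in rad3∆. Windows within 50 kb of an end rose by 0.40 log2 units (0.54, 0.32 and 0.34 on slides 1, 2 and 3; exact permutation p = 0.10; camera adjusted p = 7.2e-31), and islands rose by 0.16 (0.29, 0.025 and 0.16; exact permutation p = 0.20; camera adjusted p = 2.4e-09). With an estimated correlation the adjusted p was 0.16 for the ends and 0.32 for the islands, so neither call held. The island rise was 0.086 with a GC correction and 0.089 without rad3∆ array 1. The other classes were not called: tRNA genes differed by 0.0065 (camera adjusted p = 0.80), ribosomal protein genes by -0.0071 (0.96), snRNA and snoRNA genes by -0.061 (0.13), LTR windows by 0.048 (0.11) and control sites by 0.040 (0.11).

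The rise at the ends differed between chromosome arms. The right arm of chromosome I read -0.85 ± 0.21 in WT and -0.0083 ± 0.066 in rad3∆ over 36 windows (SD, n = 3). Differences were 0.45 on the left arm of chromosome I, 0.42 on the right arm of chromosome II (3 windows) and 0.42 on the right arm of chromosome III. They were 0.0017 on the left arm of chromosome III and -0.12 on the left arm of chromosome II, where the slides parted (0.48, -0.094 and -0.73). Each arm of the first 4 was higher in rad3∆ on all 3 slides (exact permutation p = 0.10 for each). By distance, in a profile added after these values were seen, the difference was 0.64 ± 0.17 within 25 kb of an end (SD over 3 slides), 0.30 ± 0.04 at 75 to 100 kb, 0.27 ± 0.02 at 100 to 150 kb, 0.18 ± 0.03 at 150 to 200 kb and 0.044 ± 0.054 at 200 to 300 kb. Beyond 500 kb it was -0.034 ± 0.040. Of the 30 windows within 25 kb, 27 lay on chromosome I. None lay on chromosome II, whose probes ran from 29534 to 4491993 of a length of 4539804. At 75 to 100, 100 to 150 and 150 to 200 kb the difference was 0.37 ± 0.12, 0.34 ± 0.05 and 0.20 ± 0.04 on chromosomes I and II, but 0.16 ± 0.09, 0.14 ± 0.07 and 0.12 ± 0.05 on chromosome III.

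**Figure D5:**
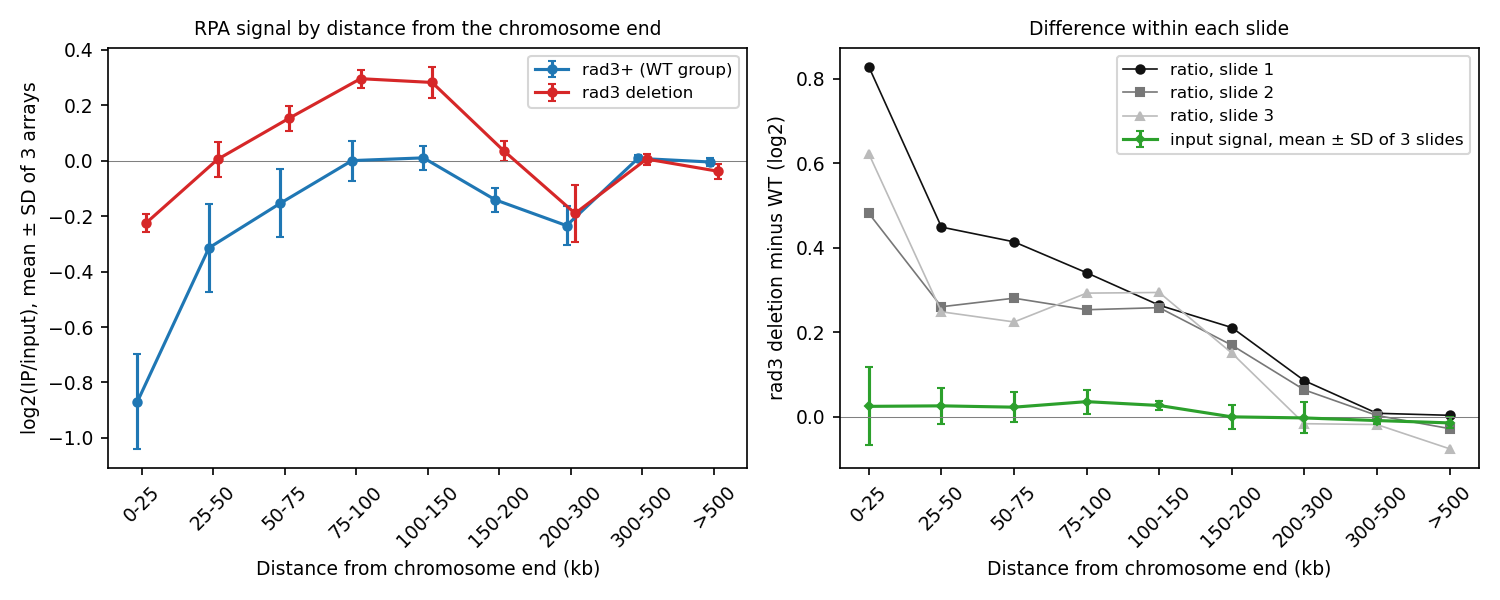
Left, mean log2(IP/input) ± SD of 3 arrays per strain by distance from the nearest chromosome end (kb), with WT in blue and rad3∆ in red. Right, rad3∆ minus WT (log2) on each of 3 slides in grey and black, with the input difference (mean ± SD of 3 slides) in green. The RPA difference declines from 0.64 within 25 kb, where 27 of 30 windows lie on chromosome I, to 0.044 at 200 to 300 kb. The input difference is at most 0.036.

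Input DNA, which follows copy number, was called at 0 windows in either direction with limma (5 higher and 28 lower at an unadjusted p under 0.05; lowest adjusted p 0.20). The windows with the lowest p were those of the deleted rad3 segment, for example 906001 to 907000 on chromosome II (0.56 ± 0.16 in WT and -5.60 ± 1.24 in rad3∆; SD, n = 3), which did not pass. The count of lower windows was 5 with the replicate block, 6 with no dye term or with scaled arrays, 9 with mode centring and 7 without rad3∆ array 1.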

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

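The tests of the input DNA, of single slides and of repeats at the right end of chromosome I, and of the position of the islands, were chosen after the result was seen; the tests of repeats at the other ends and of base composition were written before. Windows within 50 kb of a chromosome end differed between the strains by 0.40 log2 units, and A+T-rich islands by 0.16; in both cases the difference itself was tested, with camera.

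RPA near the chromosome ends was higher in rad3∆, by 0.27 log2 units over 989 windows within 200 kb (exact permutation p = 0.10). Less input DNA near the ends would raise the ratio with no change in RPA, but the input difference there was 0.019 ± 0.026 (SD over 3 slides), within its spread of 0 and not a fall the size of the rise. Probes shared with repeats elsewhere would tie the rise to windows with a second copy, counted at 100 bp or more and 90% identity. Shorter repeats were not searched. In the matching part, the 760 windows without a second copy rose by 0.23 ± 0.05, and the 43 with one by 0.25 ± 0.12. Leaving out 43 of 803 windows could hardly change the mean (0.23 ± 0.05 over all), so the weight lies on the 760. At the right end of chromosome I, outside that part, the 184 of 186 windows without one rose by 0.43 ± 0.0083. A single slide did not carry the rise, since the smallest of the slide differences was 0.24. These values argue against the 3 explanations, for repeats only as far as second copies of 100 bp or more. An effect of rad3 itself stays open as a hypothesis found on the same arrays. A difference between the strains in how far cells had replicated was not tested. Camera with an estimated correlation did not call the rise within 50 kb (adjusted p = 0.16).

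RPA at A+T-rich islands was higher in rad3∆ by 0.16, unevenly between slides (0.29, 0.025 and 0.16; exact permutation p = 0.20). A bias in base composition between arrays would raise A+T-rich probes everywhere, but island probes exceeded probes of the same GC content far from islands by 0.15 ± 0.02 more in rad3∆ than in WT, with 0.17, 0.14 and 0.13 on slides 1, 2 and 3 (per array 0.26 ± 0.13 in WT and 0.41 ± 0.12 in rad3∆; exact permutation p, which ignores the pairing by slide, 0.30); a GC correction, which also removes signal that islands owe to their base composition, left 0.086. Position near the ends does not account for the GC-matched excess either, since islands more than 200 kb from an end kept 0.14 ± 0.0064 of it. This GC-matched form was chosen after the plain rise at these islands was seen. That plain rise was 0.13 ± 0.12 (SD over 3 slides), with 0.24, 0.0052 and 0.14 on slides 1, 2 and 3. Against control intergenic sites the excess rise at islands was uneven, with 0.22, 0.0013 and 0.13 on slides 1, 2 and 3 (exact permutation p = 0.20). An effect of rad3 itself stays open. A difference between the strains in how far cells had replicated was not tested for the islands either. More RPA at origins in rad3∆ remains a hypothesis, found and tested on the same arrays, and slide 2 showed it only over GC-matched probes. Camera with an estimated correlation did not call the rise (adjusted p = 0.32).

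With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. For windows, 1 of the 10 splits gave as many calls as the real 13, and the highest other split gave 0. Of the real 13, however, 4 lay in deleted rad3 DNA. With that segment left out the real split also gave 0, of 12031 windows. For shared regions, 1 split gave as many as the real 21, and the highest other gave 0. For genes, all 10 splits gave as many as the real 0, and the highest other gave 0. For gene lists, all 10 gave as many as the real 0, and the highest other gave 1. For region classes, 8 gave as many as the real 2, and the highest other gave 4. For input DNA, all 10 gave as many as the real 0. The split with the most input calls set WT arrays 1 and 2 with rad3∆ array 2 against the other arrays. Both arrays with the IP in red then fell in 1 group, so the dye term absorbed them. The fitted difference was that of rad3∆ array 1 alone against WT arrays 1 and 2 and rad3∆ array 2. A single array likewise stands alone in every split with both red-IP arrays in 1 group, including the other one given below for the ends. Among the splits that part all 3 pairs, as the real one does, the others gave 0 windows and 0 regions, and at most 1 list and 2 classes. For the ends, the unadjusted camera p was 1.0e-31 in the real split and 1.0e-15 in the lowest other one, that of WT arrays 1 and 3 with rad3∆ array 3; with an estimated correlation the real split gave an unadjusted p of 0.022.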

How the results depend on the processing

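Alternatives that left out the deleted segment, kept protein-coding genes alone or left out slide 2 were chosen after seeing the data; all others were fixed beforehand, and the cause of a change was not tested unless stated. Of 532 values under 28 alternatives for the results that answer a comparison, 441 were labelled as kept, and 0 as reversed. Most of them were counts, which were labelled as kept when they stayed near the main count. A count has no direction, so a reversal could appear only for the rises at islands and at the ends. Enriched windows numbered 3478 in WT and 3496 in rad3∆ at a threshold of 0.3, and 218 and 220 at a threshold of 1 (513 and 599 depleted; 42 and 34 regions), by construction; 0 shared regions were higher in rad3∆ at a threshold of 1. In 2 kb windows there were 1123 and 1151 enriched windows, 1227 and 1247 depleted windows, 179 and 216 regions, 45 windows higher and 2 lower in rad3∆, and 5 shared regions higher; in 0.5 kb windows there were 565 and 587 regions, 5 windows higher and 9 shared regions higher. With the replicate block, which coincides with the slide as a block, 41 windows were higher and 2 lower, 54 shared regions were higher and 8 lower, and 5 input windows were lower; with regions called again under the slide block, 45 were higher and 9 lower. The pairing changed no other call. Windows higher in rad3∆ numbered 24 with mode centring, 8 with probes well above background, 2 with scaled arrays, and 0 with normexp, with single probes and without the deleted segment. Shared regions higher in rad3∆ numbered 35 for the union of regions, 13 with mode centring (1 lower), 11 with loess and with the GC correction, 7 with probes well above background, 3 with no dye term and 0 with normexp. Input windows lower in rad3∆ numbered 9 with mode centring and 6 with no dye term and with scaled arrays. Without both arrays of slide 2, 241 windows were higher and 48 lower, 69 shared regions were higher and 30 lower, and 54 genes were higher and 9 lower. On slides 1 and 3 alone, dye orientation coincides with the slide. That fit is thus a paired one, with fewer residual degrees of freedom than the main fit. Its counts do not show that slide 2 hid differences. With protein-coding genes alone, 1 gene was higher; the fit then covered fewer genes. The ribosomal protein list was not called (0 lists in WT and 0 in rad3∆) with the GC correction, probes well above background or an estimated correlation; normexp called 1 list, that of the histones, for the strain difference. An estimated correlation left 0 classes in WT, 0 in rad3∆ and 0 for the difference, with the rises at islands (0.16) and ends (0.40) as before. In the deleted segment the input difference, whose size the floor of the rad3∆ arrays sets, was -5.37, but -1.98 with normexp, which adds an offset of 50 to both channels. Over the whole rad3 gene, the fitted ratio in rad3∆ was 0.73 and reversed to -0.068 with normexp. With probes well above background it was -0.34, from the probes of the gene outside the deleted segment alone and so not the same quantity; that segment keeps no probe there and has no input difference. Loess has no value for input. Leaving out each array in turn gave 1535 to 2322 enriched and 2144 to 2578 depleted windows and 284 to 303 regions in WT, and 1792 to 2371, 1723 to 2624 and 308 to 369 in rad3∆. For the strain difference it gave 0 to 39 windows higher and 0 to 1 lower, 0 to 56 shared regions higher and 0 to 11 lower with a median difference of -0.046 to 0.041, 0 genes either way, and 0 input windows higher with 0 to 7 lower. Enriched genes ranged from 1171 to 1486 in WT and 1359 to 1560 in rad3∆, depleted genes from 1654 to 1767 and 1368 to 1733. Lists called were 0 to 1 in WT, in rad3∆ and for the difference, and classes 4 in WT, 3 to 4 in rad3∆ and 2 to 5 for the difference. The island rise ranged from 0.089 to 0.22, the rise at the ends from 0.30 to 0.48 and the input difference in the deleted segment from -5.79 to -4.61. Replicate 3 alone has the IP in the red channel, so without either of its arrays the dye term absorbs the other one: both settings then gave the same window and class differences (island rise 0.16, 4 windows higher), from replicates 1 and 2 only, and are not separate checks. Signal over background was lowest on rad3∆ array 2 (79.6% of IP probes well above background). Without that array 39 windows and 56 shared regions were higher, but with probes well above background 8 and 7, so these counts do not show that low signal limited the calls.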

Other observations

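The comparisons in this paragraph and the next were not among those fixed beforehand. Chromosome III carried more RPA than chromosomes I and II. More than 500 kb from an end, windows of chromosome III read 0.31 ± 0.08 in WT and 0.22 ± 0.06 in rad3∆ (SD, n = 3), and those of chromosomes I and II together read -0.059 ± 0.015 in WT and -0.082 ± 0.041 in rad3∆. Windows within 50 kb of the centromeres, placed at the widest gap between probes away from the ends, were high on chromosomes I and II: 0.47 ± 0.09 and 0.39 ± 0.04 in WT, and 0.31 ± 0.07 and 0.26 ± 0.06 in rad3∆. The differences of -0.16 and -0.13 had the same sign on all 3 slides (exact permutation p = 0.10 for each). On chromosome III these windows read 0.35 ± 0.0085 in WT and 0.23 ± 0.04 in rad3∆, close to the rest of that chromosome, with a difference of -0.12 that also had the same sign on all 3 slides (exact permutation p = 0.10). Windows 10 kb apart correlated at 0.60 in WT and 0.51 in rad3∆, and windows 50 kb apart at 0.22 and 0.13. Differences in level between chromosomes and between their parts were not removed and can add to these values. How far RPA spreads along DNA was therefore not tested.

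Taken singly, 3 of 298 islands were higher in rad3∆ and 0 were lower with limma (58 higher and 1 lower at an unadjusted p under 0.05). They lay on chromosome I at 608030 between nab3 and spo20, where the signal went from -0.96 ± 0.12 to 0.16 ± 0.39 (SD, n = 3), on chromosome II at 4440670 beside ecl3 (0.17 ± 0.06 to 1.09 ± 0.16) and on chromosome III at 2428820 (0.43 ± 0.36 to 1.24 ± 0.28), each with a limma adjusted p of 0.036. The islands on chromosomes II and III lay 99.1 and 24.1 kb from the right ends of the reference sequence. Over the last 50 kb these right arms rose by 0.42 each (3 windows on chromosome II). Islands within 200 kb of an end rose no more than control sites there (0.36 ± 0.24 and 0.35 ± 0.11, SD over 3 slides). Over probes of the same GC content, their excess was 0.13 ± 0.15, a spread too wide to tell it from 0. The difference was positive at 64.4% of islands and at 49.1% of control sites. The mitochondrial genome, which RPA does not coat, read -0.84 ± 0.36 in WT and -0.73 ± 0.29 in rad3∆ (SD, n = 3; exact permutation p = 0.60), while its input lay 4.65 to 6.19 log2 units above the nuclear median. The ura4 gene, a common selection marker, had more input DNA in rad3∆ on each slide (0.32, 0.28 and 0.49 for the window from 116001 to 117000 on chromosome III) without passing limma (adjusted p of 0.9998), and a ratio that was lower by 0.62 without passing either.

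A hypothesis, whose test was written before its result was seen, was that islands with little RPA in WT gain most in rad3∆, as dormant or late origins might. Islands were ranked by the WT arrays of the other slides, and those with the lowest values were compared with those with the highest, in 3 groups of like size, minus the same contrast at control sites. The contrast was 0.18 ± 0.17 (SD over 3 slides), with 0.35, 0.014 and 0.18 on slides 1, 2 and 3. The slides are too far apart to tell whether the hypothesis holds.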
